A study of Mus musculus with 6 samples.

How the data were processed

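RNA from 6 samples of THP-1 macrophages was sequenced, 3 control and 3 with melittin. Per the labels' protocols, total RNA was extracted with chloroform and libraries were made with the NEBNext Ultra II RNA kit for Illumina. Per the submitters' processing notes, the genome build was GRCh38. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here.

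The deposited annotated table gives raw read counts per gene and library, made by the authors, with gene identifiers, names, coordinates, lengths and Gene Ontology terms. It also gives FPKM values, which the authors made by dividing each count by the gene length in the table and by the library's total count in the same table: over values with at least 20 counts this relation held within a relative deviation of 2.2e-09. A further deposited table holds the same FPKM values, within 3.5e-06. Of the 20036 genes, 4062 had 0 counts in every library and 629 had no name. All identifiers were human, so the mouse reference at hand was not used here, and gene names and coordinates are those of the deposited table.

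Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (12029 genes), libraries were scaled with TMM factors, and the groups were compared with glmQLFit and glmQLFTest, a two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are CPM with the SD over 3 libraries of a group. An SE of a log2 fold change is that change, without its sign, divided by the square root of the quasi-likelihood F statistic. It was derived from the test and not estimated by the model. TMM factors were about 1.08 in controls and 0.92 in melittin libraries. A single count corresponded to 0.0471 to 0.067 CPM, and where a count was 0 the limit given is that of 3 counts, which covers counting error only.

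Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 34 lists with at least 5 tested genes; camera with an estimated correlation and fry were alternatives. The design, the 36 gene lists, the alternatives and the rule for named genes were set before the data were examined. That rule took the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 1 CPM and non-overlapping groups, 19 key genes fixed in advance, and for each list up to 4 passing members with the smallest adjusted p, or up to 2 of its most abundant members where none passed. Other genes in the text were chosen after their values were seen, as were the members listed as the exceptions of a list. Some genes that this rule selects are not reported here.

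Before replicates were averaged they were compared. Over genes with a summed count of at least 20 in a pair of libraries, the chi-square per degree of freedom was 1.73 to 1.76 between controls and 2.23 to 3.92 between melittin libraries, against 165.0 to 197 across groups. All pairs thus differed by more than sampling noise and each library was counted as 1 replicate. The first principal component of log2 CPM held 88.3% of the variance and separated the groups. The labels give no batch, date or culture number, so a difference in handling between the groups cannot be told apart from melittin.

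Genes that overlap were compared with the others, since reads in an overlap may be left out of the counts. Of 20036 genes, 2767 overlap another gene of the table on the same strand, and these had a median of 22 counts over the 6 libraries and were tested in 44.3% of cases. Genes overlapping only on the opposite strand (4087) had a median of 951 counts, and genes with no overlap (13182) a median of 324.5. Of 727 list genes, 76 overlap a gene on the same strand, among them ALDOA with 142 counts in all, GABARAP with 6 and HSPE1 with 580, while others such as C3 (98826 counts) were high. Whether the low values reflect the counting or low expression was not tested. CD68 (1 count in all) overlaps no gene of the table, and its low value is unexplained here. Reads shared between near-identical copies, and between antisense genes, cannot be assigned with certainty either.

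The steps were tested on simulated data in which 200 of 12029 genes were changed. The test recovered 85.2% of genes changed 1.5-fold, 90.3% changed 2-fold and 100% changed 4-fold, all with the right sign, and 7.11% of its calls were false. A simulated changed list was called and 0 of 100 unchanged lists were. In the simulation genes varied independently of each other, so it does not check the preset inter-gene correlation. It also changed far fewer genes than the 76.4% called in the data, so scaling and error rates under so wide a change were not tested.

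Alternatives to the main comparison were size factors from the median of ratios, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 3 libraries, each replicate left out in turn, a block for the replicate number, a test against 1.5-fold (glmTreat), and limma on log2 of the deposited FPKM with 1 or 0.1 added, with genes at 1 FPKM or more in 3 libraries or without that filter. After the data had been seen, further steps were added: counts of genes changed at least 2-fold under each setting, the comparison of overlapping genes, an offset that removes the trend of expression on gene length in each library, library sizes without the 20 most abundant genes, camera over Gene Ontology terms, and a scan of expression along chromosomes in windows of 15 genes.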

Results

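Gene expression was measured by RNA sequencing in macrophages made from THP-1, a human acute monocytic leukaemia line that PMA, a phorbol ester, drives into an adherent macrophage-like state. Cells in the lower chamber of a Transwell (a dish divided by a porous membrane) received PMA at 100 ng/ml for 48 h, and for the melittin group tumour cells were then placed above the membrane. In this group melittin, the main lytic peptide of bee venom, was present at 3 µg/ml for the 48 h of co-culture. There were 3 control and 3 melittin libraries. The labels do not say what the control wells received or whether tumour cells were placed above them, so an effect of the co-culture cannot be separated from one of melittin. Although the organism label reads mouse, all 20036 gene identifiers in the table were human and 0 were mouse, so the values are read as human expression. Total counts were 18756654, 19597781 and 16001423 in control replicates 1, 2 and 3, and 16604440, 19521897 and 16192032 in melittin replicates 1, 2 and 3. Between 14195 and 14440 genes had at least 1 count in a library.

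The title of the series names M2 polarization, macrophage recruitment and PD-L1 blockade, and the comparison of the groups asks how melittin changed the transcripts behind these terms. Most of the transcriptome differed between the groups. Cytokine genes were among the 10 genes with the largest rise, and genes induced by interferon among the 10 with the largest fall. Among the 10 genes with the largest rise were IL23A, the specific subunit of interleukin-23, CSF2 and CSF3, the colony-stimulating factors of granulocytes and macrophages, the chemokine receptor CCR7, the chemokine CCL22, and IDO1, the enzyme that opens tryptophan breakdown. Also among these 10 were CRLF2, TCIM, SERPINB4 and IL24. IL23A went from 1.71 ± 0.44 to 254.9 ± 18.7 CPM (read counts scaled to library size; ± SD, n = 3), and CRLF2, the receptor chain for thymic stromal lymphopoietin, from 0.0628 ± 0.109 to 14.5 ± 1.24 CPM. The 10 genes with the largest fall were CXCL10, CD1E, CD1A, SLC16A9, CXCL11, FAM111B, RSAD2, IFIT1, CHRM3 and GASK1B, with log2 fold changes from −6.97 to −4.35. CXCL10, an interferon-induced chemokine, went from 16.4 ± 1.86 to 0.13 ± 0.12 CPM. SERPINB4 shares most of its sequence with SERPINB3, so the division of reads between them is uncertain.

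By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 9190 of 12029 tested genes (76.4%) passed an adjusted p of 0.05, 4578 higher and 4612 lower with melittin. Of these, 1146 were at least 2-fold higher and 1198 at least 2-fold lower. In 9316 genes (77.4%) the 3 control and 3 melittin values did not overlap, where chance gives 10%. Against a fold change of 1.5 rather than 0, 3495 genes passed. The share of passing genes that were higher was 49.8%, and 33.6% when libraries were scaled by their totals alone, a scaling that moved the median log2 fold change of all genes from −0.007 to −0.238. CXCL8 alone took 1.54 to 1.55% of the counts in control and 5.58 to 5.71% in melittin libraries. The replicates were close to each other (biological coefficient of variation 3.01%) and nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

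Transcripts of both PD-1 ligands rose with melittin. CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470566, plus strand, GRCh38), went from 2.28 ± 0.756 to 5.57 ± 0.82 CPM (SD, n = 3), a log2 fold change of 1.30 (SE 0.206, adjusted p = 2.47e-06), higher in 3 of 3 melittin libraries than in any control. It was a low transcript, with 33 to 53 counts per control library and 83 to 93 per melittin library. PDCD1LG2, which encodes PD-L2 (chromosome 9, 5510531 to 5571282), went from 4.3 ± 0.276 to 7.14 ± 0.759 CPM, a log2 fold change of 0.72 (SE 0.142). PDCD1LG2 did not pass the test against 1.5-fold (adjusted p = 0.173). Of the wider list of checkpoint ligands and inhibitory receptors, 11 of 19 tested members rose and 5 fell (16 passed when adjusted over the list alone), with a median log2 fold change of 0.47. LILRB1, an inhibitory receptor for class I molecules, rose from 17 ± 0.525 to 82.1 ± 2.15 CPM and NT5E, the ecto-nucleotidase CD73, from 866.9 ± 0.681 to 1198 ± 11 CPM, while LGALS9 (galectin-9) fell by 1.10 and SIRPA, the receptor of CD47, by 0.57 on the log2 scale. The list as a whole did not pass the camera test (adjusted p = 0.153).

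M2-type marker genes moved in both directions. Among those that fell were the scavenger receptors CD163 and MSR1. CD163, the haemoglobin scavenger receptor (chromosome 12, 7470811 to 7503893, minus strand), went from 76.5 ± 3.97 to 9.89 ± 0.826 CPM, 7.72-fold lower (adjusted p = 1.1e-23), and MSR1 from 215.9 ± 1.5 to 30.8 ± 2.27 CPM, 7.03-fold lower. FN1, which encodes fibronectin, fell by 0.85 on the log2 scale. VSIG4, a complement receptor, and STAB1, both chosen after their values were seen, had log2 fold changes of −3.01 and −2.13. Among those that rose were IL10, from 0.12 ± 0.123 to 3.72 ± 1.34 CPM, CCL22, from 0.284 ± 0.122 to 11.5 ± 0.929 CPM, TGFB1, from 449.8 ± 6.18 to 873.9 ± 20.5 CPM and IL1RN, the interleukin-1 receptor antagonist, from 609.3 ± 9.5 to 2103 ± 17.3 CPM. The lectin CD209 rose by 0.51 on the log2 scale and missed the test against 1.5-fold and that on FPKM without a filter (adjusted p = 0.0557). MRC1, which encodes the mannose receptor CD206, had 8, 6 and 3 counts in the controls and 3, 3 and 0 with melittin, and ARG1 had 3 counts in all controls together and 0 with melittin, so neither was tested and no difference was detectable at this depth.

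Over the M2-type list, 8 of 17 tested members rose and 7 fell (15 passed when adjusted over the list alone). The median log2 fold change was −0.16, the mean 0.19, and the camera test, which compares a list with all other genes, gave no shift (direction down, adjusted p = 0.948). The median was above 0 without control replicate 1, 2 or 3 (0.205, 0.14 and 0.12) and without melittin replicate 3 (0.19), and at 0.51 over genes with at least 1 CPM in 3 libraries. These settings also change which genes are tested (12176 to 12289 with a replicate left out, against 12029). The change of sign can thus not be laid to the values of the library left out alone. It was lower with libraries scaled by their totals alone (−0.39), without a low-count filter (−0.30), without the 20 most abundant genes in the library sizes (−0.295) and with the trend on gene length removed (−0.24). The direction given by camera turned to up in the 4 cases with a replicate left out and with libraries scaled by their totals alone. Markers of macrophage differentiation fell in 10 and rose in 6 of 18 tested members (median −0.43, camera adjusted p = 0.163). There CSF1R, the receptor of macrophage colony-stimulating factor, went from 722.2 ± 10.2 to 235.1 ± 2.98 CPM, while CHI3L1 and ITGAX (CD11c) rose by 0.69 and 0.90 on the log2 scale. CD68, a common marker of macrophages, had 0 counts in the controls and 1 with melittin, a level too low to read.

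**Figure D1:**
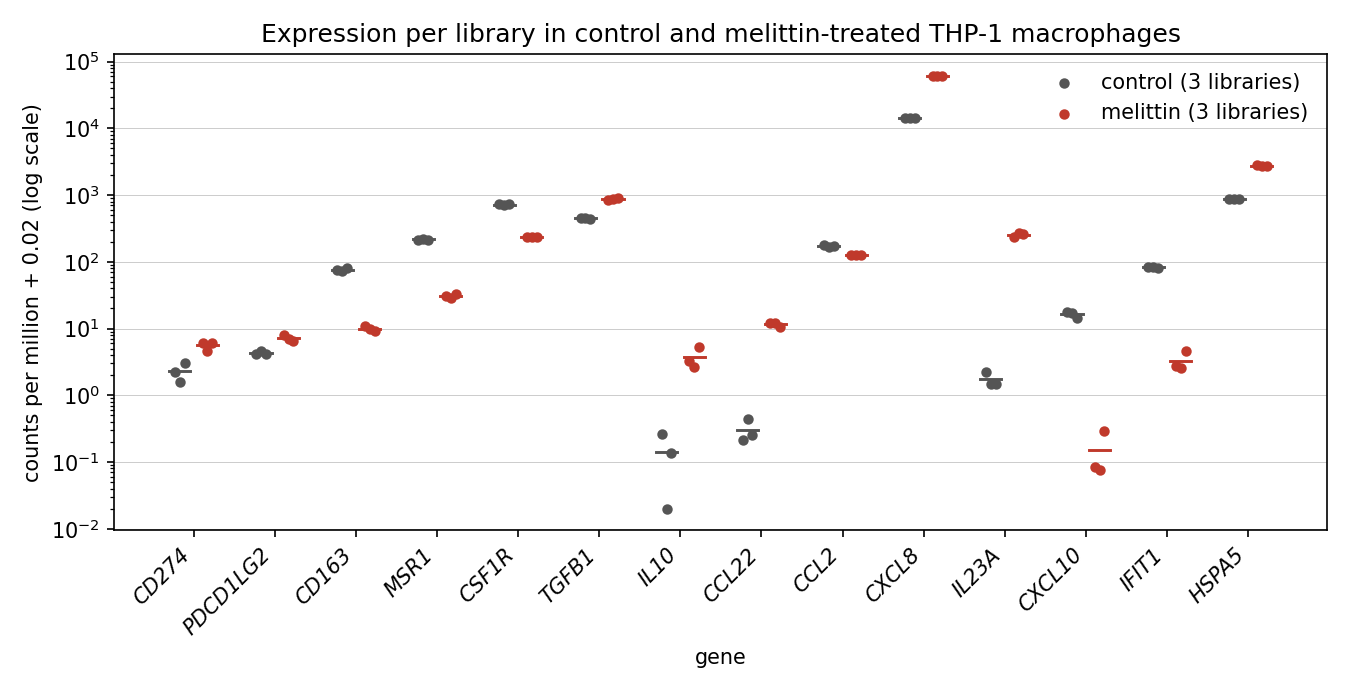
CPM plus 0.02 on a log axis for 14 genes in each of 3 control (grey) and 3 melittin (red) libraries, with a bar at the group mean. CD163 lay near 76.5 CPM in controls and 9.89 CPM with melittin, and IL23A near 1.71 and 254.9 CPM.

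M1-type markers rose in 14 and fell in 4 of 20 tested members (18 passed when adjusted over the list alone), with a median log2 fold change of 1.36 (camera adjusted p = 0.000975). With an estimated correlation the list did not pass (adjusted p = 0.0742 with an estimated correlation). CXCL8, which encodes interleukin-8, went from 14300 ± 74.8 to 61170 ± 549 CPM, IL1B from 12350 ± 59.3 to 23740 ± 321 CPM, IL6 from 0.421 ± 0.189 to 5.39 ± 0.967 CPM and the co-stimulatory ligand CD80 from 0.325 ± 0.0364 to 3.07 ± 1.2 CPM. TNF went the other way, from 134.7 ± 5.55 to 105.4 ± 1.39 CPM, a fall by 0.35 on the log2 scale that missed the test against 1.5-fold. CD86 had a log2 fold change of −0.30 (adjusted p = 0.164) and passed when libraries were scaled by their totals alone (−0.53) and without melittin replicate 2 (−0.52, adjusted p = 0.0359). CXCL10 and CXCL11, chemokines induced by interferon, were among the members that fell.

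Most tested chemokines and growth factors that draw neutrophils and monocytes were higher with melittin, while the monocyte attractants CCL2, CCL7 and CCL8 and the vascular growth factor VEGFA were lower. Of the recruitment list, 13 of 20 tested members rose and 7 fell (20 passed when adjusted over the list alone), with a median log2 fold change of 1.93 (camera adjusted p = 0.00117; adjusted p = 0.0742 with an estimated correlation). CXCL5 went from 758.8 ± 9.08 to 5210 ± 138 CPM, CXCL2 from 55.8 ± 3.29 to 624.0 ± 13.1 CPM, CCL20 from 1736 ± 13.3 to 5328 ± 73.3 CPM and CSF1, the ligand of CSF1R, from 419.7 ± 6.96 to 1420 ± 26.1 CPM. CCL2 went from 173.1 ± 4.66 to 127.9 ± 0.955 CPM, a fall by 0.43 on the log2 scale that missed the test against 1.5-fold. CCL8 and CCL7, chosen after their values were seen, had log2 fold changes of −2.69 and −1.33. CCR2, the receptor of CCL2, had 3 counts over the controls and 2 over the melittin libraries and was not tested. CCL3 was listed at 2.82 CPM in controls, and its near-identical copy CCL3L3 at 281.7 ± 6.73 CPM in controls and 2230 ± 22.7 CPM with melittin, so the reads of this pair cannot be assigned with certainty to either gene.

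Interferon-stimulated genes fell while NF-kB targets rose. Of 32 tested interferon-stimulated genes 26 fell and 3 rose (29 passed when adjusted over the list alone), with a median log2 fold change of −1.69 (camera adjusted p = 4.15e-09; adjusted p = 0.0519 with an estimated correlation). OAS3 and OAS2, sensors of double-stranded RNA, went from 247.4 ± 6.53 to 37.1 ± 2.65 CPM and from 191.3 ± 0.474 to 31.3 ± 1.14 CPM. IFIT3 was 7.82-fold and SAMD9L 8.68-fold lower with melittin, and IFIT1 went from 82.8 ± 1.11 to 3.27 ± 1.13 CPM. IRF7, BST2 and ISG20 were the 3 members that rose, IRF7 by 0.19 on the log2 scale (adjusted p = 0.048) with overlapping groups, and 2 members rose with libraries scaled by their totals alone and with the length trend removed. Of 25 NF-kB targets 20 rose and 4 fell (24 passed when adjusted over the list alone), with a median of 0.80 (camera adjusted p = 1.03e-07; adjusted p = 0.0519 with an estimated correlation). CXCL1, CXCL2, CXCL8 and CCL20 were among those that rose, and TNF, NFKB1, NFKBIE and RELB were the members that fell. STAT3-linked genes rose in 15 and fell in 4 of 19 members (median 0.83, camera adjusted p = 0.00056; adjusted p = 0.0917 with an estimated correlation), among them PIM1, HIF1A, BCL6 and SOCS3, the last 6.54-fold higher. Immediate early genes rose in 17 and fell in 2 of 21 members, and in 14 and 6 with libraries scaled by their totals alone (median 0.83, and 0.60 with that scaling; camera adjusted p = 0.000108; adjusted p = 0.0742 with an estimated correlation), with DUSP5, EGR2, IER5 and ZFP36 between 2.56-fold and 3.01-fold higher.

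**Figure D2:**
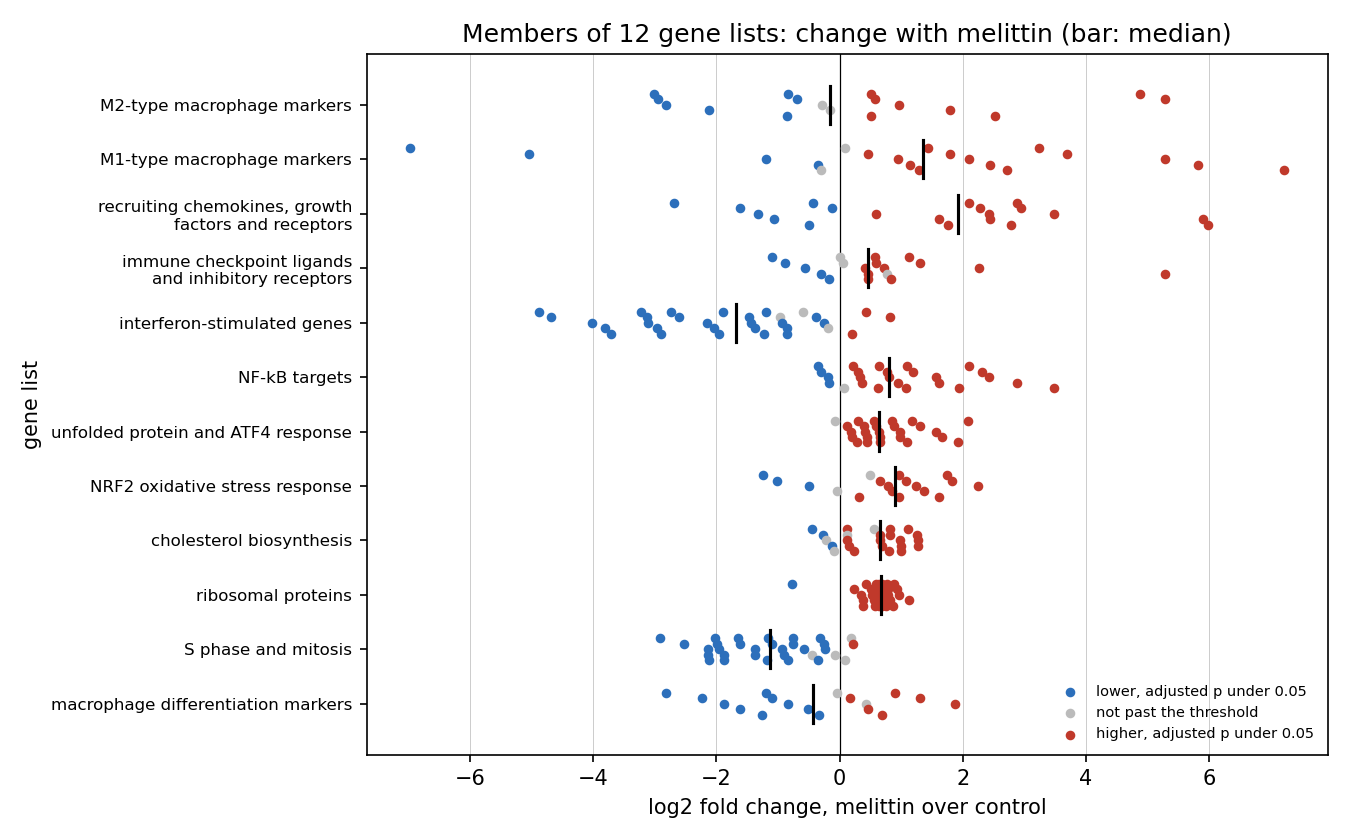
Log2 fold change with melittin of every tested member of 12 gene lists, with red and blue points for members higher or lower at an adjusted p under 0.05, grey points for the others and a black bar at each list's median. The median of the interferon-stimulated genes lay at −1.69 and that of the NF-kB targets at 0.80, and M2-type markers spread from −3.01 to 5.29.

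Most members of the unfolded protein, NRF2 and hypoxia lists rose. In the unfolded protein and ATF4 list 25 of 26 members rose and 0 fell (median 0.65, camera adjusted p = 6.54e-09; adjusted p = 0.0519 with an estimated correlation), and 19 rose and 2 fell with libraries scaled by their totals alone. HSPA5, the endoplasmic reticulum chaperone BiP, went from 868.1 ± 8.44 to 2755 ± 30.4 CPM, DDIT4 was 4.23-fold, HERPUD1 2.46-fold and HSP90B1 1.81-fold higher. NRF2 targets rose in 13 and fell in 3 of 18 members (median 0.90, camera adjusted p = 0.00252; adjusted p = 0.0844 with an estimated correlation). Among them FTL, the ferritin light chain, went from 2376 ± 16.9 to 7962 ± 74.2 CPM and GCLM, a subunit of the enzyme that limits glutathione synthesis, from 23.1 ± 1.24 to 109.3 ± 3.06 CPM. Hypoxia-response genes rose in 12 and fell in 3 of 17, and in 9 and 5 with libraries scaled by their totals alone (median 0.49, and 0.255 with that scaling; camera adjusted p = 0.0111; adjusted p = 0.109 with an estimated correlation), with BHLHE40, NDRG1, P4HA2 and MXI1 among those that rose. Cytosolic heat shock genes rose in 10 and fell in 1 of 13 (median 0.32, camera adjusted p = 0.0275; adjusted p = 0.144 with an estimated correlation), and this list did not pass with libraries scaled by their totals alone (adjusted p = 0.219, 8 higher and 5 lower) or with the trend on gene length removed (adjusted p = 0.0987). HSPA1B was 4.05-fold higher, while HSPA8 fell by 0.38 on the log2 scale. HSPA1B and HSPA1A are near-identical and share reads. Of the metallothioneins only 3 were tested, of which MT2A (8 ± 1.64 to 26.0 ± 5.58 CPM) and MT1F rose, too few for a list test.

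Genes of cholesterol biosynthesis rose in 17 and fell in 3 of 24 members (median 0.66, camera adjusted p = 0.000182; adjusted p = 0.0742 with an estimated correlation), and 13 rose and 8 fell with libraries scaled by their totals alone. MSMO1 was 2.41-fold higher, INSIG1 1.99-fold and SQLE 1.58-fold. Genes of LXR and cholesterol efflux went both ways, with 5 higher and 8 lower of 15 (median −0.10, mean 0.06, camera adjusted p = 0.688). There the exporter ABCA1 fell by 0.63 on the log2 scale and its relative ABCG1 rose from 2.09 ± 0.505 to 10.3 ± 2 CPM.

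Ribosomal protein genes rose in 33 of 34 members, and RPS23 fell (34 passed when adjusted over the list alone; median 0.67, camera adjusted p = 8.38e-13; adjusted p = 0.109 with an estimated correlation). With libraries scaled by their totals alone 31 rose and 1 fell. RPL13 went from 327.4 ± 7.1 to 712.7 ± 25 CPM, and RPL3 was 1.73-fold higher. Shorter genes were higher with melittin in general: over 12029 genes the log2 fold change and gene length had a Spearman correlation of −0.185, and the median ran from 0.24 in the shortest of 8 length classes to −0.20 in the longest. Nuclear genes of oxidative phosphorylation rose in 18 and fell in 2 of 27 (median 0.31, camera adjusted p = 0.0114; adjusted p = 0.205 with an estimated correlation), a call that ended with libraries scaled by their totals alone (11 higher, 7 lower, median 0.08, adjusted p = 0.0998) and with the length trend removed (14 higher, 6 lower, median 0.18, adjusted p = 0.248). COX4I1 went from 165.2 ± 4.59 to 330.7 ± 1.84 CPM, and UQCRC1 rose by 0.69 on the log2 scale. Mitochondrially encoded transcripts rose in 3 and fell in 7 of 13 (median −0.09, camera adjusted p = 0.356). MT-CO3 and MT-CYB fell by 0.52 and 0.51 on the log2 scale, and MT-ND4 rose by 0.32, a call that ended with the length trend removed (0.03, adjusted p = 0.235) and on FPKM without a filter (0.09, adjusted p = 0.139). With libraries scaled by their totals alone 1 rose and 9 fell (median −0.32), and with the length trend removed 0 rose and 12 fell (median −0.41) and the list passed as lower (adjusted p = 7.29e-05). MT-ND2 had a log2 fold change of 0.23 in the main comparison. It was near 0 with libraries scaled by their totals alone (−0.006, edgeR adjusted p = 0.823). With the length trend removed it passed as lower (−0.118, edgeR adjusted p = 1.07e-05).

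Genes of S phase and mitosis fell in 27 and rose in 1 of 32 members (28 passed when adjusted over the list alone; median −1.12, camera adjusted p = 7.23e-05; adjusted p = 0.0742 with an estimated correlation). The replication helicase subunits MCM4 and MCM3 were 2.13-fold and 2.23-fold lower, RRM2, a subunit of ribonucleotide reductase, went from 24.5 ± 3.3 to 6.57 ± 0.916 CPM and CDC20 from 14.6 ± 0.702 to 3.29 ± 0.376 CPM. The member that rose was MCM6, which did not pass with libraries scaled by their totals alone. Summed over the list the level was low, 490 CPM in controls and 294.0 CPM with melittin. Targets of p53 went both ways, with 7 higher and 9 lower of 19 (median −0.04, camera adjusted p = 0.78). The cell-cycle inhibitor CDKN1A rose from 1058 ± 9.95 to 1774 ± 57.1 CPM, BAX and TNFRSF10B rose, and SESN1 fell by 0.74 on the log2 scale. Glycolysis genes gave 9 higher and 7 lower of 21, and 6 and 11 with libraries scaled by their totals alone (median 0.03, and −0.20 with that scaling; camera adjusted p = 0.688), with ENO2 3.09-fold and SLC16A3 1.58-fold higher and PKM 1.78-fold lower.

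Among genes of the endolysosomal system the cathepsins parted. CTSL went from 700.8 ± 10.8 to 2694 ± 25 CPM and CTSB from 1261 ± 12.9 to 2470 ± 51.8 CPM, while CTSS was 2.08-fold and the acid lipase LIPA 2.81-fold lower. The lysosome and phagocytosis list had 16 higher and 9 lower of 28, and 10 higher and 13 lower with libraries scaled by their totals alone (median 0.19, and −0.04 with that scaling; camera adjusted p = 0.153). The autophagy list had 8 higher and 4 lower of 15, and 6 and 6 with that scaling (median 0.19, and −0.04; camera adjusted p = 0.153), with ATG2A, MAP1LC3B, WIPI1 and GABARAPL1 between 1.62-fold and 2.37-fold higher. Genes of membrane repair, ESCRT and annexins, listed because melittin forms pores in membranes, were higher in 6 and lower in 10 of 19, and in 4 and 14 with libraries scaled by their totals alone (median −0.26, and −0.49 with that scaling; camera adjusted p = 0.219). MYOF, a ferlin, was 4.35-fold, ANXA4 2.5-fold and ANXA1 1.75-fold lower, and ANXA6 2.10-fold higher. Inflammasome genes were higher in 9 and lower in 4 of 14 (median 0.76, camera adjusted p = 0.126, and 0.0423 with libraries scaled by their totals alone), with CASP1 2.06-fold and NINJ1, a mediator of plasma membrane rupture, 2.31-fold higher and NEK7 1.74-fold lower.

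Complement genes rose in 7 and fell in 2 of 11 (median 0.65, camera adjusted p = 0.0341; adjusted p = 0.205 with an estimated correlation). This call ended without control replicate 2 (adjusted p = 0.054), without melittin replicate 3 (adjusted p = 0.0569) and without a low-count filter (adjusted p = 0.081). C3 rose from 758.4 ± 9.5 to 1123 ± 12.9 CPM, and ITGAM and CD55 by 1.31 and 0.83 on the log2 scale. Class II presentation genes rose in 4 and fell in 0 of 5 (median 1.12, camera adjusted p = 0.0674, 0.0211 with libraries scaled by their totals alone and 0.0402 without a low-count filter), from low levels: CD74 went from 65.7 ± 3.16 to 102.6 ± 1.46 CPM, HLA-DQB1 from 0.186 ± 0.0119 to 2.04 ± 0.131 CPM, and HLA-DRB1 and HLA-DMA rose. Class I presentation genes were higher in 8 and lower in 4 of 14, and 5 and 6 with that scaling (median 0.23, and −0.005; camera adjusted p = 0.328), with HLA-E 2.48-fold and B2M 1.41-fold higher and ERAP1 and TAP2 2.09-fold and 1.9-fold lower. HLA genes share sequence and vary between people and lines, so their counts carry this uncertainty. Matrix genes and proteases were higher in 12 and lower in 9 of 25, and 10 and 12 with that scaling (median 0.18, and −0.05; camera adjusted p = 0.328). MMP10 went from 145.1 ± 3.36 to 945.8 ± 14.6 CPM, MMP1 was 2.12-fold higher and ADAMTS1 7.64-fold lower.

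Markers of other cell states and cell types were measured in the same libraries. Dendritic cell markers were higher in 8 and lower in 4 of 12 (median 0.57, camera adjusted p = 0.137). CCR7, CD83 and the transcription factor IRF8 (12.2 ± 1.14 to 92.4 ± 2.52 CPM) rose, and CD1A and CD1E of the CD1 family fell. Markers of undifferentiated monocytic cells were higher in 6 and lower in 2 of 12 (median 0.73, camera adjusted p = 0.328), at a summed 68.7 CPM in controls and 85.5 CPM with melittin, with S100A9, S100A8 and the granule protease PRTN3 (0.0906 ± 0.0869 to 2.23 ± 0.25 CPM) higher and LYZ lower. Of 24 prostate and epithelial tumour markers 5 were tested, 1 higher and 2 lower (median −0.13, camera adjusted p = 0.847). STEAP1 went from 24.3 ± 0.815 to 16.2 ± 0.934 CPM and FOLH1 (PSMA) from 1.01 ± 0.0984 to 0.159 ± 0.109 CPM. EPCAM, KRT18 and KRT19 had 0 counts in all 6 libraries, which allows up to 0.0281 CPM, and KLK3 (PSA) had 0 in controls and 2 with melittin. Of the fibroblast and endothelial markers 5 were tested, with COL1A1 higher and PDGFRA lower (median −0.01, camera adjusted p = 0.937), and COL1A1 did not pass with libraries scaled by their totals alone or in the 3 FPKM settings. None of the 16 haemoglobin and lymphocyte markers was tested, the highest count being 13. Replication-dependent histone genes, whose transcripts mostly but not always lack poly(A) tails, gave 3 higher and 3 lower of 10. Of these, 5 passed when adjusted over the list alone (median −0.09, mean 0.32, camera adjusted p = 0.688). H1-2, H2BC5 and H2BC8 were higher and H2AC6 lower.

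Scaling libraries by their totals alone lowered the median of each list by about the shift of all genes, so counts of higher members are smaller and those of lower members larger, or equal, with that scaling. Over the 34 tested lists 15 passed the camera test with its preset correlation of 0.01. With a correlation estimated for each list 0 passed (lowest adjusted p 0.0519), and 12 lists had an unadjusted p under 0.05. Among the 15, the estimate was above 0.01 in some lists, such as interferon-stimulated genes (0.0193) and ribosomal proteins (0.225). It was below 0.01 in others, such as NF-kB targets (−0.0185), the unfolded protein list (−0.0284) and M1-type markers (−0.0189). For lists with an estimate below 0.01 the lost call does not come from a larger correlation. With a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated one it takes them from the 6 libraries in 2 groups, which gives a larger p for the same statistic. For M1-type markers the unadjusted camera p went from 0.000258 to 0.0163. That 0 lists passed is thus no evidence that their members are correlated. The test fry, which asks only whether a list's own genes moved in a common direction, passed 30 lists. The number of members passing was the same over all tested genes and adjusted over the list alone for all tested lists except 2, the heat shock list (11 and 12) and the histone list (6 and 5).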

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

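The length offset and the library sizes without the 20 most abundant genes were chosen after seeing the data; the other settings were planned. The count of 9190 genes stayed within 1.5 times under every setting (7764 to 9570, and 8857 to 9147 with a replicate left out) except the test against 1.5-fold, which called 3495 genes, 1761 higher and 1734 lower, because it asks for a larger change. The split of higher against lower calls depended on the scaling: 49.8% were higher with TMM, 33.6% with library totals alone, and 34.0%, 33.9% and 33.7% on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, which keep the library totals as scale. On FPKM 2645 (+ 1) and 2635 (+ 0.1) genes were higher, 307, 458 and 308 (no filter) at least 2-fold higher, and 514 at least 2-fold lower with 1 added, filtered or not. These settings change scale, test, filter and constant together, and the cause was not tested. With the test against 1.5-fold 5 M2-type members rose and 4 recruitment members fell. The M2-type list, not called by camera under any setting (adjusted p 0.881 to 0.979 with a replicate left out), gave 0.00229 (down) with fry. The M1-type and recruitment lists gave 0.0742 each with an estimated correlation and passed elsewhere (1.36e-06 to 0.00321 and 4.45e-07 to 0.0023). Of 2932 settings of 155 named genes 2889 kept direction and call and 32 lost the call with the direction kept. These losses were in the test against 1.5-fold, apart from CD209, MT-ND4 and COL1A1, which lost it elsewhere too. The call was gained in 6 settings (all CD86), and the direction turned in 5, all for MT-ND2. This gene was at −0.006 with library totals (edgeR adjusted p = 0.823) and in the 3 FPKM settings (limma adjusted p = 0.843 to 0.892). In these settings it was near 0 and its call was lost. Only with the length offset did it pass as lower (−0.118, edgeR adjusted p = 1.07e-05). Library totals, which FPKM also keeps as scale, moved the median of all genes from −0.007 to −0.238, and MT-ND2 moved with it. The cause of the remaining changes was not tested. The replicate numbers did not pair the samples (correlations of same-numbered deviations −0.046, 0.018 and −0.019), and a replicate block called 9050 genes, 9037 of them shared with the main comparison, and changed no list call. DESeq2 gave no adjusted p for 5896 genes. The alternative restricted to protein-coding genes was not run, since no column gives the gene type. Depth limits low genes such as CD274, MRC1 and ARG1.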

Other observations

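Gene Ontology terms of the deposited annotation were tested after the data had been seen. Of 1457 terms with 15 to 300 tested genes 12 passed the camera test, 9 higher and 3 lower. With an estimated correlation, and the fewer degrees of freedom that come with it, 0 passed (camera adjusted p = 0.809 for each). Genes of endoplasmic reticulum to Golgi vesicle-mediated transport were higher in 65 and lower in 23 of 106 (adjusted p = 0.0159), and those of cytoplasmic translation, a term that includes ribosomal protein genes, higher in 75 and lower in 3 of 87 (adjusted p = 5.38e-15). Genes of microtubule-based movement, which include kinesins and dyneins, were lower in 42 and higher in 8 of 58 (adjusted p = 0.0442), and those of regulation of nucleotide-excision repair lower in 19 and higher in 3 of 25 (adjusted p = 0.0442).

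Common reference genes moved in opposite directions, a point of practical weight for quantitative PCR on these cells. ACTB was at 5801 to 5995 CPM in controls and 2566 to 2761 CPM with melittin, while GAPDH was at 1364 to 1381 and 1875 to 2049 CPM. FTH1, the ferritin heavy chain, was at 624.4 to 727.4 CPM in controls and at 1217, 2180 and 2769 CPM in melittin replicates 1, 2 and 3, a spread that FTL (7893 to 8041 CPM) did not have. Melittin replicate 1 was also apart in RPS27 (463.9, 672.2 and 676.6 CPM in melittin replicates 1, 2 and 3) and MT-ND3 (397.7, 638.7 and 621.9 CPM). CDKN2A and MTAP, neighbours on the short arm of chromosome 9, had 0 counts in 106674227 over all libraries, and CDKN2B had 1; this stretch is known to be deleted in THP-1.

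Of the tests below, the range of the ribosomal median, the length offset, the library sizes without the 20 most abundant genes, the comparison of list medians with all genes and the window scan were chosen only after the results had been seen. Of the 10 splits of the 6 libraries into 3 and 3 only the real one, 1 of 10, called as many as 9190 genes, and the highest of the others called 0. For the gene lists the real split called 15, again 1 of 10, and the highest of the others 11. Each of the other splits had more controls on one side and more melittin libraries on the other. It thus kept part of the difference between the groups, and the rest entered the spread within its sides. The 0 genes and up to 11 lists called there are therefore no chance rates. The splits cannot decide whether the calls of the real one arose by chance. With 10 splits no share under 0.1 can be reached.

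The fall of interferon-stimulated genes beside the rise of NF-kB targets is a pattern to follow up, since both sets are often induced together. Abundant genes such as CXCL8 would move all other genes of a library alike. In the 9 pairs of a control and a melittin library the interferon median minus the median of all genes was −1.882 to −1.686 on the log2 scale. That of the NF-kB targets was 0.798 to 0.907. A shift common to all genes cancels in these differences and so cannot make them. They restate the medians of the lists, however, and are no further support for the pattern. Leaving the 20 most abundant genes out of the library sizes (medians −1.818 and 0.664) decides nothing here, since it also moves all genes alike. The trend with gene length was too small to be the whole cause, with medians from 0.24 in the shortest to −0.20 in the longest of 8 length classes. The list medians were −1.806 and 0.961 after the length offset, which could hardly have removed either change. A candidate explanation, as an untested hypothesis, is that melittin lowers interferon signalling, which interferon added to separately grown cultures would test, and an unlabelled difference in culture or co-culture between the groups stays open beside it.

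Ribosomal protein genes rose nearly together, and they are short and abundant, so technical recovery was weighed. Their median log2 fold change was 0.67, and 0.589 after the trend with gene length was removed. That trend was too small to be the whole cause, with a median of 0.24 in the shortest of 8 length classes. The offset could thus hardly have removed the rise, and it covers only the gene lengths of the deposited table. Recovery of short transcripts that varies between libraries would spread the melittin libraries, as seen for RPS27, MT-ND3 and FTH1, but the range of the median of the ribosomal list was 17.9% of the difference between the groups, with melittin replicate 1 the highest. An effect of melittin on translation genes may remain, as an untested hypothesis that protein synthesis measured in separately grown cultures would bear on, and a recovery difference common to all melittin libraries stays open.

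Neighbouring genes near 40 Mb of chromosome 1 stood out by mean level over the 6 libraries. The 15 genes from 39838110 to 40771603 (TRIT1 to NFYC) had a median expression percentile of 94.7 among 11339 genes. CAP1 was at 16560, SMAP2 at 4456, PPT1 at 2558 and ZMPSTE24 at 1955 CPM. Not all members were high, with MYCL at percentile 47.5, EXO5 at 50.3, ZFP69B at 66.6 and COL9A2 at 75.4. Of 1000 shuffled gene orders 3 held a window as high (permutation test, p = 0.004), which argues against chance order. The highest shuffled window reached 95, however, and the next separate window of the data 94. A gain of copies in this line could produce such a run, and so could clustering of active genes. No DNA data were used here, and no biological explanation was tested.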
